A study of Drosophila melanogaster with 3 samples.

How the data were processed

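ChIP-seq with an anti-GFP antibody was done on whole pupae of a fly line that expresses CG4496 fused to eGFP, in 3 biological replicates, per the labels. The pupal stage and sex are not stated there. The chromatin was sonicated, per the labels, and a possible control experiment is named. Per the text files deposited with the lists, the peaks of each replicate derive from its own alignments to dm6 and 1 further file, which also went into the tracks of fold change over control and whose role is not stated. The thresholded lists derive from 1 more file, of unstated role, than the ranked lists. The lists are peak lists ranked by the irreproducible discovery rate (IDR), and the thresholded lists hold the entries past the authors' threshold. The aligner and the peak caller are not given in the sources used here. For each peak, the authors deposited an interval and a summit offset in bp and, as scores, a scaled IDR score and a signal value. The scale of the signal value is not stated. It is the authors' own value and was used only to rank peaks within a list. A conservative IDR list of the whole experiment, derived from the alignments of all 3 replicates per the deposited text, was used as an alternative. It holds 9825 peaks. Which replicates it compares is not stated, and the other lists of the whole experiment were not analysed here. There was no unassigned sample and no unused column of per-sample values.

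The lists name dm6, and the reference was Release 6 of the genome with Ensembl genes and RefSeq genes. No peak passed the end of its arm. Of the 13968 protein-coding genes on the arms found in both annotations, 13966 had the same start, end and strand. Only chromosome arms 2L, 2R, 3L, 3R, 4, X and Y were used. Coordinates are 1-based. Transposable element entries of the annotation were left out as genes and TSS, a choice made after seeing the annotation, and the alternative with them is in the closing section.

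Peaks of different replicates were called shared when they overlapped by at least 1 bp. Expected shares come from 1000 seeded circular shifts within each arm. Peaks that overlap were merged, and regions with a peak of all 3 replicates form the consensus. The summit of a region is the median of the summits of the strongest peak of each replicate. A gene was called bound when a summit lay within 500 bp of any of its TSS. Intervals for shares of peaks are exact binomial 95% intervals and cover counting error only. Summits were placed in order in 5' UTR, coding exon, 3' UTR, non-coding exon, intron or between genes; non-coding exons were added as a class after the annotation was seen. There are 31 gene lists, of which some are symbol patterns, and 8 gene classes. Symbols were matched to the annotation directly or, for 28 entries, through a RefSeq synonym that pointed to 1 gene, and 14 unmatched entries were left out. The class of pre-miRNA genes had no member in the annotation, which leaves 7 classes. Fisher's exact tests compared each list with all other protein-coding genes, and each class with all other genes. Motif and 8-mer tests compared the 100 bp at the summit with 100 bp centred 300 bp away, on a side drawn with a fixed seed, in the same region.

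The lists, the motifs, the tests, 69 alternatives and the rule for named genes were fixed before the data were examined. The rule takes CG4496, the protein-coding gene with a TSS nearest to the summit of each of the 20 regions with the highest mean rank percentile (within 500 bp), the 3 nearest genes of the 5 strongest regions over 1 kb from any TSS, and the 4 bound members with the highest percentile in each list or class that passed. The GC content of summits, their share in coding exons, the position of summits upstream of the TSS, the comparison of TATAAA with words of the same composition and the counts of peaks in windows of 2L were added after seeing the data. So were the genes named beside those of the rule, as sharing a region or neighbouring it.

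Several of the steps were tested on simulated data. With 41.1% of the 5999 peaks of replicate 1 kept in place, 43.7% were found shared, where shifts gave 2.38%. All 5760 simulated regions were recovered in 3 of 3 lists. Of 5 planted gene lists all 5 were called, and of 200 random lists 0 were, over 13968 genes. With an 8-mer planted in a part of 3848 regions, a test of all 8-mers on all arms called it and 8 others. Of these 8, 7 share at least 6 bases with it. The search on chromosome 2 with a test on other chromosomes was not simulated. In regions with no planted signal, 0 of 28 motifs were called. These regions were placed away from the real summits and were not built to hold a GC difference between summit and flank. Motif calls under such a difference were therefore not tested by simulation. The software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

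Alternatives covered the overlap that counts as shared, the peak set (the conservative list, 2 of 3 replicates, the stronger part of each list, 50% reciprocal overlap), each replicate left out, TSS windows of 250 and 1000 bp, the TSS used per gene, the ranked entries as background, and window and flank sizes of the motif tests. Precision is limited by 3 replicates of 1 group and by lists that carry no read counts. Whole pupae mix many tissues, so a peak can come from a few of them.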

Results

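CG4496 is a protein of the fruit fly Drosophila melanogaster. Its binding sites on chromatin were mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in whole pupae of a transgenic line that makes CG4496 fused to the green fluorescent protein eGFP. An anti-GFP antibody was used to recover the DNA bound by the fusion protein. The data were 3 biological replicates of 1 group, so the design asks where the protein is found and how well the replicates share its sites. It holds no comparison between conditions. The thresholded list of replicate 1 held 6000 peaks, that of replicate 2 held 8117 and that of replicate 3 held 6314, of which 5999, 8115 and 6310 lay on the chromosome arms. The longer ranked lists of the same replicates held 95885, 89094 and 95995 entries. These files give peaks and not reads, so the sequencing depth behind each list is unknown.

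The strongest CG4496 sites were shared by all replicates, and the weak ones less often. In the strongest signal decile of each list, 99.5% ± 0.414 (SD, n = 3) of the peaks overlapped a peak of both other replicates. The share was 64.5% ± 13.8 in decile 5, lowest in decile 9 (19.96% ± 10.4) and 26.6% ± 7.17 in decile 10. In decile 10, 65.3, 44.8 and 59.1% of the peaks of replicates 1, 2 and 3 overlapped a peak of at least 1 other replicate. Over whole lists and all 6 ordered pairs, a mean of 70.7% of peaks overlapped a peak of the other list, from 60.2% of replicate 2 peaks found in replicate 1 to 81.4% of replicate 1 peaks found in replicate 2. Lists shifted at random along each chromosome arm shared a mean of 2.73%, and none of 1000 shifts came near the observed mean (one-sided permutation p = 0.001, the smallest these draws can give). Merging the lists gave 9667 regions, of which 6067 held a peak of at least 2 replicates and 3848 held a peak of all 3. The 3848 regions, with a median width of 323 bp, are called the consensus regions from here on. Replicate 2, which had the longest list, also had the most regions of its own, 1958, against 760 for replicate 1 and 882 for replicate 3.

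**Figure D1:**
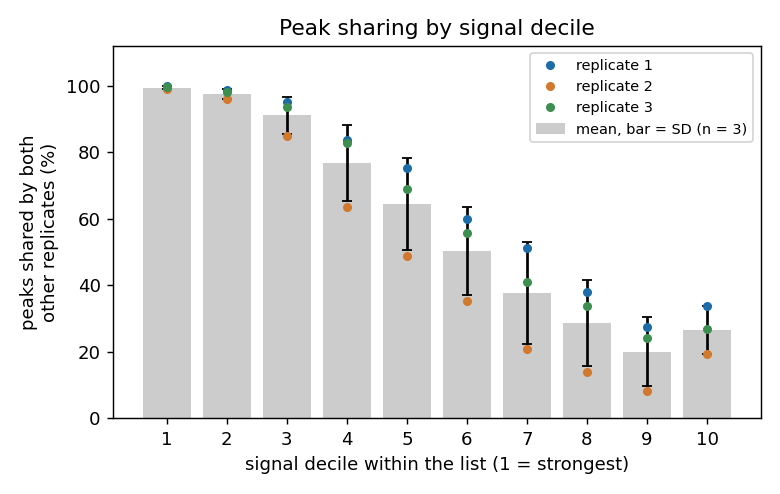
Share of thresholded peaks that overlap a peak of both other replicates (%, vertical axis) by signal decile within each list (horizontal axis, 1 is the strongest); points are replicates, bars their mean and error bars the SD (n = 3). The mean was 99.5% in decile 1, 19.96% in decile 9 and 26.6% in decile 10.

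CG4496 peaks lay near promoters more often than shifted peaks did, and seldom in coding sequence. A transcription start site (TSS) lay within 500 bp of 42.3% ± 1.70 (SD, n = 3) of peak summits, and of 1680 of the 3848 consensus summits (43.7%, exact 95% interval 42.1 to 45.2%). The replicate values were 44.1% (42.9 to 45.4%), 40.7% (39.7 to 41.8%) and 42.1% (40.9 to 43.3%). Peaks shifted at random along the arms gave a mean of 13.5%, a 3.13-fold ± 0.121 difference (one-sided permutation p = 0.001 in each replicate, the smallest these draws can give). Entries of the ranked lists outside the thresholded peaks had a TSS within 500 bp in 17.0% ± 0.821 of cases. When summits were sorted by gene structure alone, 2060 consensus summits (53.5%) lay in introns, 1232 (32.0%) between genes, 2.99% in non-coding exons, 372 (9.67%) in 5' untranslated regions (UTRs), 47 (1.22%) in 3' UTRs and 22 (0.572%) in coding exons. Of the arms, 42.2% are introns, 31.6% lie between genes, 3.29% are 5' UTRs, 16.3% coding exons and 4.81% 3' UTRs. With summits within 500 bp of a TSS set apart, that class took 43.7% of the consensus summits and 13.27% of the arms. Introns then held 40.4% of all consensus summits and 39.1% of the arms, and DNA between genes 12.99% and 28.3%. These are shares of all summits and all bases, so the intron shares do not compare what remains outside the TSS class. Of the 2168 remaining summits, 1555 lay in introns and 500 between genes. The low share in coding sequence was seen in the replicates (1.43% ± 0.248, n = 3), whereas 23.4% ± 1.81 of the ranked entries outside the thresholded lists had a coding summit. The coding share was 2.03% in the authors' conservative list and 0.223% when only the stronger part of each replicate list was used.

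Around promoters the summits sat upstream of the start site. Of the 1555 consensus summits within 500 bp of a protein-coding TSS, 1191 (76.6%) were upstream, and the shares in the replicates were 70.3%, 69.8% and 73.3%. The 100 bp just upstream of the TSS held 447 of these summits and the next 100 bp held 443, against 200 in the first 100 bp downstream. Among the 500 strongest consensus regions the position was sharper. There, 105 of 239 summits (43.9%) lay 100 to 200 bp upstream, and 35 (14.6%) lay closer on the upstream side.

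**Figure D2:**
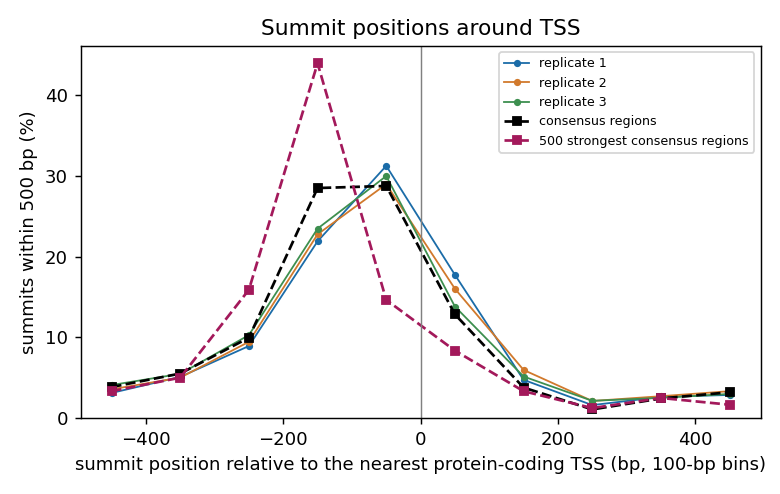
Position of summits relative to the nearest protein-coding TSS (bp, horizontal axis, negative is upstream) as a share of the summits within 500 bp (%, vertical axis), in bins of 100 bp, for the 3 replicates, the consensus regions and the 500 strongest of them. The strongest regions peak 100 to 200 bp upstream, with 43.9% of their summits.

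Promoter share changed little with peak strength. It was 45.3% ± 1.47 (SD, n = 3) in the strongest quintile of the peaks and 40.7% ± 2.83 in the weakest. The difference was 2.42, 6.10 and 5.39 percentage points in the replicates (mean 4.64 ± 1.95). The quintiles between lay at 40.3% ± 1.53, 43.3% ± 2.91 and 42.0% ± 1.14, so there was no steady order. The X chromosome carried more peaks than the large autosomal arms, with 57.4 ± 8.98 per Mb against means of 47.1 (3R) to 53.0 (3L) on the arms of chromosomes 2 and 3. Within a replicate, the ratio of X to chromosomes 2 and 3 was 1.13, 1.13 and 1.19. Per 1000 TSS the ratio was 1.24 ± 0.0380. Chromosome 4 had 2.47 ± 1.54 peaks per Mb, with 4, 5 and 1 peaks in the replicates and no consensus region; with only the stronger part of each list, its ratio to chromosomes 2 and 3 fell from 0.0484 to 0.0192. The Y chromosome had 1, 0 and 1 peaks. The ranked lists already held 1.21 ± 0.0292 times as many entries per Mb on X, and 0.0679 ± 0.0402 times as many on chromosome 4, as on chromosomes 2 and 3.

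Of the 20 strongest consensus regions, 16 had a protein-coding TSS within 500 bp of the summit, against 239 of the 500 strongest. Strong ranked entries missing from the thresholded lists are not among these regions. Such entries in introns of ush (places 7, 10 and 5 in the ranked lists) and Lk6 (14, 12 and 12) lay 1429 and 966 bp from a TSS. Percentiles given with regions are means of the signal rank percentile within the replicate lists (100 is the strongest; n = 3). The top region in every replicate, on X at 2703738 to 2704035 (dm6), lay between genes with its summit 40 bp from a TSS of Ugalt, the UDP-galactose transporter. Next came a region on 3L at 19590484 to 19590749, 91 bp from a TSS of CG14100 (99.98 ± 0.00486). On 3L at 5139365 to 5139635, the summit lay 104 bp from a TSS of Tcs5 and 120 bp from one of CHMP2B, a subunit of the ESCRT-III complex (99.93 ± 0.0231). A region in the 5' UTR of PNPase, the mitochondrial polynucleotide phosphorylase, was at 31404526 to 31404795 on 3R (99.92 ± 0.0365). Further regions lay 132 bp from a TSS of mRpL41 (2R, 15217609 to 15217872; 99.91 ± 0.0190), 80 bp from one of mRpL23 (3L, 2373475 to 2373737; 99.73 ± 0.145) and between the starts of Art3 and mRpS10 (3R, 15229410 to 15229656, 127 and 130 bp away; 99.80 ± 0.0298). CenG1A, an Arf GTPase-activating protein, shared its region with mRpS23 (2L, 13835339 to 13835585, 101 and 391 bp away). CG7601 shared one with CIA30, an assembly factor of respiratory complex I (3R, 29736709 to 29736971, 99 and 121 bp). Other genes nearest to the 20 strongest regions were CG18549, eIF6, Elp5, ph-p, tank and CG3552, all within 500 bp of the summit, and CG4496 itself. The lowest of these, at CG3552, stood at 99.72 ± 0.128.

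Of the 20 strongest regions, 4 had no protein-coding TSS within 500 bp. One lay in an intron of CG11050 on 2L (6612472 to 6612917), 1036 bp from its TSS, with DIP-iota and CG34345 as the next genes, 8977 and 10389 bp away. Its percentile was 99.97 ± 0.00270. A region between genes on 2R (13035226 to 13035465; 99.84 ± 0.0204) was 11915 bp from a TSS of CG13323, 14315 bp from one of CG13324 and 38218 bp from one of Su(z)2, a Polycomb group gene. A region in an intron of CG32486 on 3L (3060671 to 3060931; 99.78 ± 0.0969) lay 5730 bp from CG16753, 8150 bp from CG1271 and 10030 bp from a start of CG32486. The remaining one, on 3R at 29214302 to 29214569 (99.78 ± 0.0286), was 5723 bp from eEF1gamma and 113 bp from the start of the non-coding gene lncRNA:CR31044. The next strongest distal regions were in an intron of CG32772 on X (4910063 to 4910711; 99.71 ± 0.0727), with CG6927 and CG4041 as neighbours, and between genes on 2L (2202272 to 2202528; 99.68 ± 0.107), nearest to CG31668, COX7AL2 and CG33124.

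CG4496 peaks also lay on the CG4496 gene itself. The gene (FBgn0031894) spans 7185461 to 7190010 on the minus strand of 2L and has 3 annotated transcripts, which start at 7190010 and 7188068. A region at 7187928 to 7189131 was number 5 in strength among the 3848 consensus regions (percentile 99.93 ± 0.0759, n = 3), with its summit at 7188124, in an intron and 56 bp upstream of the inner start. Its peak ranked 4 of 5999, 2 of 8115 and 11 of 6310 by signal in the replicates. A further region over the outer start, at 7189608 to 7190134 with its summit in the 5' UTR, had a percentile of 98.66 ± 0.874. Within 10 kb of the gene lay 4 more consensus regions: in the 5' UTR of CG4497 (7194431 to 7194648; 93.92 ± 3.01), in an intron of CG4502 (7199664 to 7199819; 82.3 ± 3.68) and at 2 sites between genes (61.3 ± 12.4 and 51.6 ± 18.9). The window of 24550 bp held 14, 9 and 11 peak summits in the replicates, against means of 1.08, 1.46 and 1.14 in other windows of that length on 2L. Of 958 other windows, 0, 8 and 2 held as many. The line carries an insertion that targets CG4496, per the labels, so DNA copies and binding are not separated by these files.

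**Figure D3:**
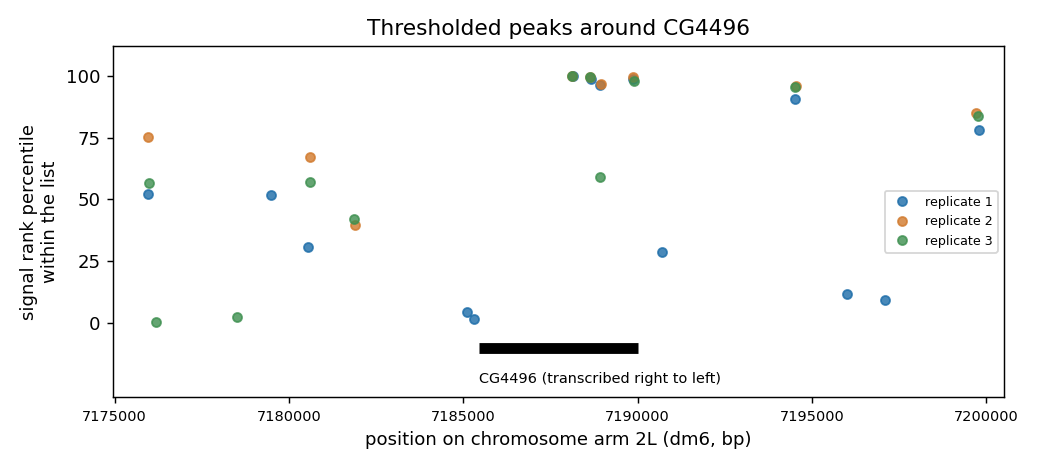
Thresholded peaks within 10 kb of CG4496 on chromosome arm 2L; the horizontal axis is the dm6 position (bp) and the vertical axis the signal rank percentile of the peak within its list, with 1 point at the summit of each peak, coloured by replicate, and the gene as a black bar. The strongest peaks lie in the intron and at the starts of the gene, up to a place of 2 of 8115.

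CG4496 was found at the promoters of 1844 of 13968 protein-coding genes (13.2%), and these genes were not spread evenly over functions. The gene lists were compared with all other protein-coding genes, whether active in pupae or not. Targeting particular to CG4496 is therefore not separated from what active promoters have in common. Of the 31 gene lists, 7 were bound more often than the other protein-coding genes and 2 less often, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 31 lists. Cytoplasmic ribosomal protein genes had the lowest adjusted p. Of 93, 46 were bound (49.5%, against 12.96% of other genes; odds ratio 6.57, Fisher's exact adjusted p = 9.52e-16), and in the separate replicates the bound share was 62.0% ± 5.08 (n = 3), where 19.0, 22.6 and 19.2% of all protein-coding genes were bound. RpL7 (93.3 ± 2.41), RpS27 (92.7 ± 3.37), RpS28b (92.1 ± 1.77) and RpL34b (91.4 ± 0.598) had the highest rank percentiles. By contrast, 12 of 73 mitochondrial ribosomal protein genes were bound (16.4%, Fisher's exact adjusted p = 0.666), and so were 9 of 52 genes of translation initiation and elongation factors (adjusted p = 0.666).

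Among genes of transcription and chromatin, 3 lists passed. The general transcription and splicing machinery had 12 of 37 genes bound (odds ratio 3.17, Fisher's exact adjusted p = 0.0107), led by TfIIA-L (88.5 ± 3.13), the TFIID subunit gene Taf4 (87.9 ± 1.01), the splicing factor gene U2af50 and the RNA polymerase subunit gene Polr2H. Insulator and architectural proteins had 8 of 21 bound (odds ratio 4.06, Fisher's exact adjusted p = 0.0132). Chro, which encodes a chromodomain protein, was the strongest (99.71 ± 0.106), before Trl, which encodes the GAGA factor (94.3 ± 1.17), Cp190 (85.8 ± 5.53) and Nup98-96 (76.0 ± 7.30). The trithorax group also had 8 of 21 bound (odds ratio 4.06, Fisher's exact adjusted p = 0.0132), led by brm, the ATPase of the Brahma remodelling complex (98.4 ± 0.334), Trl, sls, which encodes a titin-like protein, and the demethylase gene Utx. Calls depended on the definition. With 50% reciprocal overlap the transcription and splicing call was lost (odds ratio 2.17, Fisher's exact adjusted p = 0.177, range 0.00107 to 0.177 over 12 alternatives). The insulator call was lost there too (odds ratio 3.15, Fisher's exact adjusted p = 0.0861, range 0.0147 to 0.135) and with the conservative list (odds ratio 2.12). The trithorax call was lost under 4 alternatives (adjusted p 0.00373 to 0.787 over 12), among them the comparison of genes with equal TSS number by a Cochran-Mantel-Haenszel test (odds ratio 3.55, adjusted p = 0.130, n = 13968 genes). In the others its odds ratio was 3.43 at 250 bp, 2.68 with the stronger part of each list and 1.35 with 1 TSS per gene. In the comparison of genes with equal TSS number, here and below, the genes with the most TSS were pooled in 1 stratum. For those genes the number was therefore matched only in part. The Polycomb group, with 6 of 21 bound, did not pass (Fisher's exact adjusted p = 0.152).

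The Hippo, autophagy and ecdysone response lists passed as well. Of 16 Hippo pathway genes, which control tissue growth, 8 were bound (odds ratio 6.60, Fisher's exact adjusted p = 0.00338), with app (94.8 ± 1.34), Mer (86.1 ± 2.34), ex (77.4 ± 6.30) and mats (68.0 ± 8.74) at the top. Autophagy had 9 of 23 genes bound (odds ratio 4.24, Fisher's exact adjusted p = 0.0106), led by Atg2 (90.1 ± 1.07), Atg7 (89.5 ± 3.30), Atg17 and Atg18a. Genes that respond to ecdysone, the steroid that drives metamorphosis, had 10 of 30 bound (odds ratio 3.30, Fisher's exact adjusted p = 0.0132). Among them were Eip93F (94.9 ± 2.20), a transcription factor gene, E23 (94.7 ± 1.01), which encodes an ABC transporter, the cell death gene hid (86.7 ± 6.29) and the nuclear receptor gene ftz-f1 (83.9 ± 10.8). The ecdysone call was lost among genes of equal TSS number (odds ratio 1.77, Cochran-Mantel-Haenszel adjusted p = 0.499, n = 13968 genes), with 1 TSS per gene and at 1000 bp (range 0.00337 to 0.836 over 12 alternatives). The Hippo odds ratio ranged from 3.68 with 1 TSS per gene to 11.6 at 1000 bp and 11.8 without replicate 3. The Hippo call was lost with 1 TSS per gene (Fisher's exact adjusted p = 0.0966), at 250 bp (0.0699) and with the stronger part of each list (0.137; lowest of 12 alternatives 3.03e-05), and the autophagy call with the conservative list (0.0651; lowest 0.00107).

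Receptor and cuticle genes were bound less often than other genes. Of 180 odorant and gustatory receptor genes, 0 had a consensus summit at a promoter (Fisher's exact adjusted p = 2.39e-10), and of 8 Hox genes 0 had one, which did not pass (adjusted p = 0.819). Of 122 genes in the cuticle protein list, 3 were bound (odds ratio 0.164, Fisher's exact adjusted p = 0.000723). They were Cpr50Cb, Cpr73D and Cpr, and Cpr encodes cytochrome P450 reductase rather than a cuticle protein. For neuropeptides the count was 1 of 28 (Fisher's exact adjusted p = 0.369), for the proteasome 3 of 48 (adjusted p = 0.387), for muscle structure 3 of 32 and for neuronal function 4 of 31. The circadian clock list had 4 of 13 bound (Fisher's exact adjusted p = 0.229), heat shock 6 of 24 and the EGFR and Ras pathway 6 of 23 (both adjusted p = 0.287). The other lists lay between 10.8 and 21.2% bound and did not pass.

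**Figure D4:**
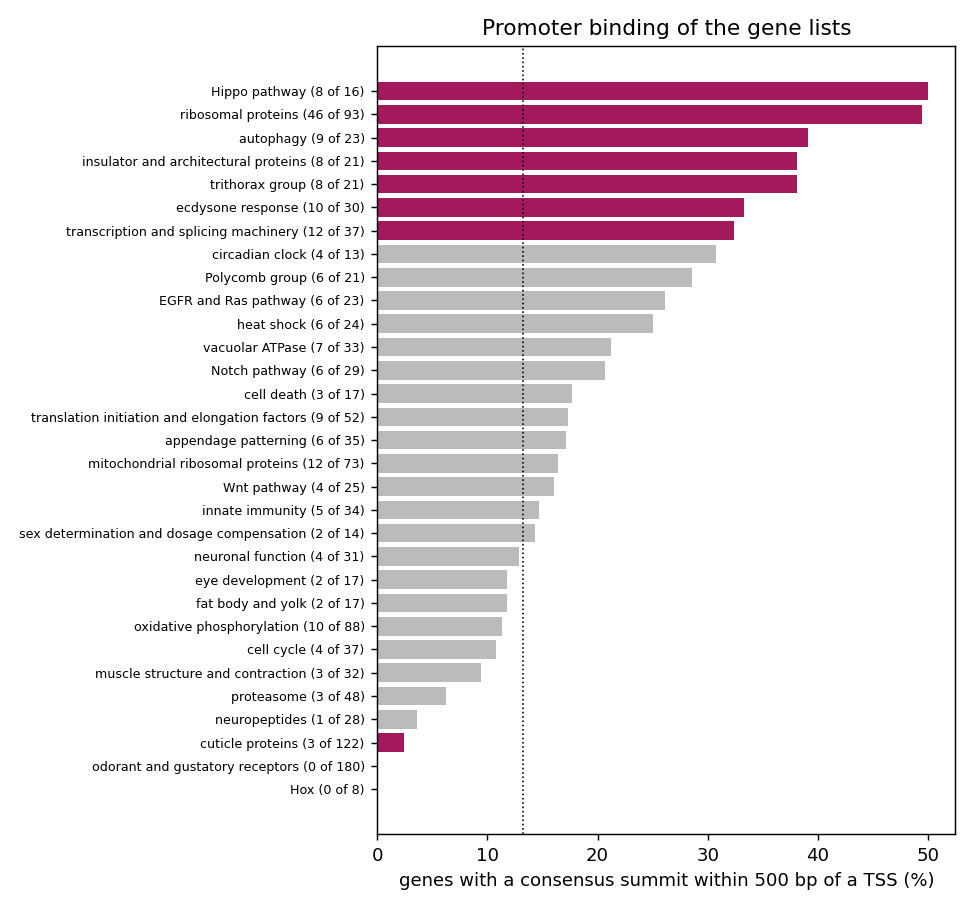
Share of the genes of each list with a consensus summit within 500 bp of a TSS (%, horizontal axis), with bound and total genes in brackets; coloured bars have an adjusted p under 0.05 by Fisher's exact test and the dotted line marks all protein-coding genes (13.2%). Hippo pathway and ribosomal protein genes had the highest shares; the odorant and gustatory receptor list, at 0 of 180, also passed but has no bar to colour.

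Of 7 gene classes, 6 were bound less often than other genes. Against 11.2% of all 18277 genes, consensus summits were at 179 of 3289 non-coding RNA genes (5.44%, odds ratio 0.403, adjusted p = 5.63e-35), 16 of 290 tRNA genes (5.52%, adjusted p = 0.00115), 8 of 269 snoRNA genes (2.97%, adjusted p = 2.90e-06), 3 of 330 pseudogenes (adjusted p = 6.13e-13), 1 histone gene (0.870% of the class, adjusted p = 5.19e-05) and 0 of 99 rRNA genes (adjusted p = 2.73e-05), by two-sided Fisher's exact tests adjusted over 7 classes. For snRNA genes, 2 of 32, Fisher's exact test did not pass (adjusted p = 0.574). The bound histone gene was His2Av, a variant gene outside the histone cluster. A region on 2L (21426637 to 21426743), nearest to His1:CG33804 and His3:CG31613 and 221 bp from a TSS, is not counted here. It was past the lowest thresholded score in the ranked lists of all 3 replicates but is missing from the thresholded lists. The strongest of the tRNA sites was near tRNA:Tyr-GTA-1-8 on 3R (97.0 ± 0.729), and lncRNA:CR44463 on 2R was the first of the non-coding RNA genes, at the region shared with mRpL41. The best-ranked snoRNA gene was snoRNA:Psi28S-2949 (89.7 ± 2.17) and the best-ranked pseudogene CR15345 (73.9 ± 9.50). The tRNA call was lost under 3 of 12 alternatives, among them genes of equal TSS number (Cochran-Mantel-Haenszel adjusted p = 0.224, n = 18277 genes), and the snoRNA call at 1000 bp (Fisher's exact adjusted p = 0.599). Genes of the repeated rRNA and histone arrays are near-identical copies, and how reads from them were mapped is not given in the sources used here. The tests also counted each gene as independent. Genes in arrays are not, and neighbours can share a region, as snoRNA:Psi28S-2949 and snoRNA:Or-aca5 did on 2R (9095157 to 9095284). The adjusted p-values of such classes therefore overstate the evidence.

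CG4496 summits were marked by DNA rich in A and T. In the 100 bp around the summit the GC content was 38.8% ± 0.811 (SD, n = 3 replicate lists), against 42.8% ± 0.278 in a window 300 bp away. The difference was -2.97, -3.93 and -5.13 percentage points in the replicates. It was -6.78 points over the consensus regions, -12.2 in the 500 strongest and 1.04 in the 500 weakest of them. In the authors' conservative list the difference was -2.75 points. Distal regions (-9.32 points) differed more than TSS-proximal ones (-4.21 points). The side of the flank was drawn anew for each set, here and in the motif tests, so flank values of the 2 parts do not add up to those of all regions. Entries of the ranked lists outside the thresholded peaks went the opposite way, by 3.73 ± 0.214 points.

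**Figure D5:**
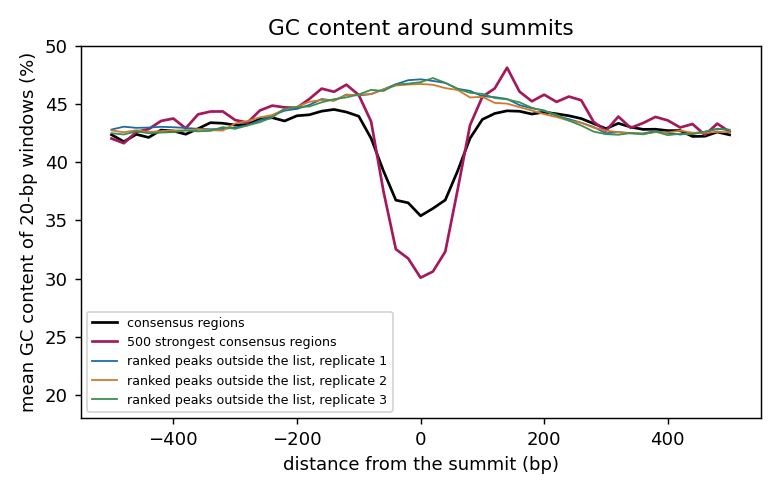
Mean GC content of 20-bp windows (%, vertical axis) by distance from the summit (bp, horizontal axis) for the consensus regions, the 500 strongest of them, and 1 in 10 ranked entries outside the thresholded list of each replicate. GC content at the summit was 35.4% for the consensus and 30.1% for the strongest regions, and 46.7 to 47.1% for the ranked entries.

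Of 28 fixed motifs, 9 were more frequent in the summit window than in the flank window of the same regions and 5 less frequent, by exact McNemar tests (two-sided, Benjamini-Hochberg adjustment over 28). The TATA box element TATAAA was found at 18.3% of summits and 10.8% of flanks (exact adjusted p = 4.37e-19), and runs of 8 A or T at 11.7 and 7.33% (adjusted p = 6.87e-10). All 15 sequences of 6 bases with the composition of TATAAA were more frequent at summits, and TATAAA was number 8 among them (log2 ratio 0.77, range 0.50 to 0.84). The homeodomain core (7.48 against 5.22%, exact adjusted p = 0.000462), initiator, GATA and forkhead sites were also more frequent, and these calls were lost under 2, 2, 4 and 6 of 12 alternatives. The site of DREF, a regulator of growth genes, lay at 35 of 1680 TSS-proximal summits and 10 of their flanks (exact adjusted p = 0.00231), and at 4 and 6 of 2168 distal ones (adjusted p = 0.880). Ohler motif 7 had 62 and 35 in the TSS-proximal set (exact adjusted p = 0.0293), and 28 and 29 in the distal set. Over all regions the DREF element call was also lost with the stronger part of each list (log2 ratio 1.28, exact adjusted p = 0.132) and a 60 bp window (1.32, 0.111), where the ratio stayed near the 1.38 of all regions. The Ohler motif 7 call was lost with the stronger part (log2 ratio 0.49, exact adjusted p = 0.375) and a flank 500 bp away (0.45, 0.144), against 0.58 over all regions. The su(Hw) site, 21 against 7 over all regions (exact adjusted p = 0.0319), had a log2 ratio of 1.58. The su(Hw) ratio was 2.42 in the distal set (exact adjusted p = 0.0124), 2.32 without replicate 2 and above 2 without replicate 3. The su(Hw) call was lost in the TSS-proximal set (5 against 2 regions, log2 ratio 1.32), with the stronger part of each list and with a 60 bp window (exact adjusted p = 0.223). CA repeats (2.08 against 4.05%, exact adjusted p = 6.35e-06) and the Pho site (4.94 against 7.02%, adjusted p = 0.000804) were less frequent at summits, and the Pho call was lost in TSS-proximal regions (log2 ratio -0.31, adjusted p = 0.352) and with a 60 bp window (-0.39, 0.0846), against -0.51 over all regions. The CA repeat log2 ratio of -0.96 was -0.32 with the conservative list. E-box CAGCTG, EcR half-site and Zelda sites were also less frequent (exact adjusted p = 0.0337, 0.0125 and 0.0337), but these calls were lost or turned under 9, 7 and 12 of 12 alternatives. Only the E-box ratio turned, in TSS-proximal regions. Where the calls were lost, the EcR half-site log2 ratio lay from -0.84 to -0.21, against -0.74 over all regions. The Zelda ratio lay from -2 to -0.40, against -1.46. The GAGA factor site was less frequent at distal summits (1.61 against 3.32%, exact adjusted p = 0.00156). At TSS-proximal summits it was found at 4.05 against 3.39%. The CTCF core was more frequent at TSS-proximal summits (89 against 53 of 1680 regions, exact adjusted p = 0.0124). The Su(H) site was less frequent at distal summits (94 against 138 of 2168 regions, exact adjusted p = 0.0123). Over all regions neither passed (exact adjusted p = 0.422 and 0.0782). Differences between the TSS-proximal and distal sets were not tested for any motif.

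A search without fixed motifs also led to A/T-rich words. Of the 10 leading 8-mers on chromosome 2, 6 were made only of A and T. Chromosome 4 was set for the test too but had no consensus region. By the same test (adjusted over 10), 8 of the 10 were more frequent at summits on chromosomes 3 and X. The leading one there was ATTTAAAA, at 5.13% of 2478 summits and 1.78% of flanks (exact adjusted p = 9.05e-10), followed by TATTTTAA (4.32 and 1.69%, adjusted p = 3.25e-07) and AAAAAAAA (12.7 and 8.11%, adjusted p = 5.11e-07). CCTGCTCC was less frequent at summits, with 3 against 13 regions (exact adjusted p = 0.0236), and CCAATTTC did not pass (adjusted p = 0.743). Which words led depended on the regions and windows used, and 1 to 4 of the 10 were shared with each alternative; with the conservative list only 1 of the 10 was made of A and T alone. With the flank of nearer GC content, chosen after seeing the data, 8 of the 10 were, and all 10 were more frequent at summits. GC content still differed there (36.3% at summits, 41.8% in the flank), so base composition was not matched. A search among words with at least 4 G or C was also chosen after seeing the data. Its 10 leading words on chromosome 2 were all less frequent at summits there. Of them, 7 passed on chromosomes 3 and X, such as CACACACA (2.10 against 4.16%, exact adjusted p = 0.000314).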

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

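The tests in this part were chosen after the lists had been seen. Strong ranked entries that no thresholded peak overlaps are a signal in data that the comparisons do not use. On the chromosome arms, 173 entries of replicate 1, 185 of replicate 2 and 160 of replicate 3 had a scaled IDR score at or above the lowest score of the thresholded list and no overlap with it. They merge into 95 regions present in all 3 replicates, of which 60 lie on 3R and 25 on 2L. Some were among the strongest of all ranked entries. An intron of ush on 2L (480942 to 481226) ranked 7, 10 and 5 in the replicates, an intron of Lk6 on 3R (11760923 to 11761169) ranked 14, 12 and 12, and an intron of larp on 3R (28326465 to 28326731) ranked 27, 35 and 36. A region between genes near tara on 3R (16224390 to 16224620) and one in an intron of trx (14283785 to 14283979) followed, at places 130, 116 and 114 and 150, 162 and 152. These genes were chosen after their values were seen. With the 95 regions added, Kdm2, kibra, Ras85D, Hsp70Ba, cwo, TfIIA-S, RpL13A, eIF4A and eIF4EHP became bound members of the gene lists, and the numbers of lists past the threshold stayed at 7 and 2. The thresholded lists derive from 1 more file than the ranked lists, per the deposited text, and its role was not tested.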

How the results depend on the processing

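Alternatives for the GC, coding and upstream shares, those with transposable elements as TSS, with the 95 added regions and with a flank of nearer GC content were chosen after seeing the data. Under the alternatives, 94 values of the main results stayed within their spread or 1.5 times the count and 21 moved. The cause was not tested unless the definition itself sets it. Of 78 genes singled out by rank, 16 lost their region under 1 alternative. With 50% reciprocal overlap these were 11, among them Mer, ex, hid, Taf4, TfIIA-L, U2af50, Nup98-96, RpL34b and Atg17, and with the stronger part of each list 5, among them Cpr50Cb and Cpr73D. The shared part of the lists was 61.5% with 50% reciprocal overlap and 81.15% among the 2000 strongest peaks. The number of regions was 9085 in the conservative list, 6067 with 2 of 3 replicates and 2244 with the stronger part of each list. The share near a TSS was 33.7% at 250 bp and 53.2% at 1000 bp, and 40.6% in the conservative list. Against ranked entries the fold was 2.49. The gap between strongest and weakest peaks was 6.70 points at 1000 bp. The X ratio was 1.21 for the stronger part and 1.24 per 1000 TSS, and the chromosome 4 ratio 0.0192 for the stronger part. With 1 TSS per gene, 4 lists were bound more often. Fixed motifs less frequent at summits numbered 1 in TSS-proximal regions, 3 with 2 of 3 replicates, 2 with a window of 200 bp and 1 with 60 bp, and 2 to 4 when replicates were left out in turn. With a 60 bp window 5 of 10 8-mers passed. On the log2 scale, DREF (-0.58) and Ohler motif 7 (-0.051) turned in distal regions, E-box CAGCTG (0.12) in TSS-proximal regions and su(Hw) (-0.19) in the stronger part, each with no call. The Zelda call was lost under all 12 alternatives, with a log2 ratio that stayed below 0 in each, from -2 (TSS-proximal regions) to -0.40 (200 bp window). Calls for ribosomal protein, cuticle and receptor genes, and for TATAAA, the A tract and CA repeats, held under all 12 run for each. None of the 12 for motifs matched base composition. With the flank of nearer GC content, GC was still 36.3% at summits and 41.8% in the flank. The motif calls that held are therefore not separated from the GC difference. The GC difference ranged from -9.52 points (stronger part) to -2.75 (conservative list), and the upstream share from 66.9% (conservative list) to 80.7% (stronger part). A flank of nearer GC content ended the initiator, Zelda, GATA, E-box CAGCTG and forkhead calls, with log2 ratios of -1.32 (Zelda, -1.46 before) and -0.33 (E-box, -0.40 before). It added a call for the CTCF core, which was more frequent at summits (166 against 114 regions). It also added calls for Su(H) (173 against 231) and Grainyhead (3 against 13), which were less frequent there. With transposable elements as TSS the TSS share was 42.9%, and with the 95 regions added the numbers of lists stayed at 7 and 2. No paired analysis was possible because there is 1 group. The lists carry no read counts, so depth cannot be set against the number of peaks.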

Other observations

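Some genes held many CG4496 regions inside their bodies. These genes were chosen after their values were seen, as the 10 with the most regions. Only consensus regions were counted. The regions missing from the thresholded lists, of which several lie inside ush and tara, were left out and could change this order. The most were in kirre (20 regions over 394149 bp), sbb (18 over 79099 bp), CHES-1-like (13 over 27048 bp) and the nuclear receptor gene Hr4 (13 over 66017 bp). Relative to the mean density over the arms, these were 1.81, 8.13, 17.2 and 7.04 times. Tet and Tlk held 12 each (4.61 and 6.15 times), ftz-f1 and shn 11 each (7.75 and 6.74 times), and Eip75B and CG1677 10 each (3.14 and 2.87 times). No test of these densities was run.

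Of the tests in this part, the one on coding flanks and the one on extra copies of the CG4496 locus were set before their results were seen, and the others after. The A/T-rich summits were weighed first. Promoter location is not the whole cause, since regions more than 1 kb from a TSS had a GC difference of -10.3 percentage points between summit and flank (95% bootstrap interval -10.9 to -9.62, 1745 regions). Coding sequence in the flanks is argued against by 3359 regions with no coding base in either window, at -5.97 points (-6.49 to -5.42). The ranked entries outside the thresholded lists had a difference of 3.73 points, which argues against a bias for A/T-rich DNA that reaches all ranked entries. A bias in the scores would move A/T-rich sites into the thresholded lists and leave the others outside. These entries therefore cannot decide on such a bias, which stays open. A preference of the protein for A/T-rich DNA, and open DNA that attracts many factors, may each underlie the pattern, and no biological explanation was tested because the design has 1 group.

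The peaks at the CG4496 locus may come in part from extra DNA copies. Ranked entries outside the thresholded lists in the window of 24550 bp around the gene had a median signal above 99.4, 98.0 and 96.8% of the windows of that length on 2L. That is what extra copies would give. The adjacent windows on both sides were also high, with a lowest percentile of 93.2, so a wider stretch of raised background is consistent with the data too. These explanations were not separated by the tests, and binding to the gene stays open beside them.

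The low number of peaks on chromosome 4 was already present before the threshold. Ranked entries per Mb stood at 0.0679 times those of chromosomes 2 and 3, which argues against the step from ranked to thresholded lists as the whole cause. Peaks per 1000 TSS stood at 0.0638 times, which argues against fewer TSS. Steps before ranking, such as read mapping, stay open as a possible explanation. A lack of binding alone would not lower the number of background entries, and the ranked lists held only 101, 59 and 26 entries there. As far as these entries are background that falls evenly over the arms, that argues against a lack of binding as the whole cause. Whether background falls evenly was not tested. Ranked entries outside the thresholded lists favoured GC-rich DNA (46.8% GC at summits, 43.0% in flanks), so these counts cannot decide the question. No biological explanation was tested directly.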
